A study of Mus musculus with 3 samples.

How the data were processed

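The series holds 3 libraries of mouse olfactory epithelia, 1 each from E18.5, P14 and adult animals of the CD-1 strain, all wildtype. Per the labels, cells were freed with papain and captured on the 10x Genomics Chromium system. The number of animals per library, their sex and the adult age are not given in the sources used here. The deposited tables hold raw counts of UMIs per gene and barcode, with no scaling, for barcodes that the authors had already filtered. The submitters' processing notes name Cell Ranger, without a version, and the mm10 genome.

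The E18.5 library had 3270 barcodes and 25166213 UMIs (median 7051 UMIs and 2685 genes per barcode), the P14 library 2317 barcodes and 9349067 UMIs (3042 and 1649), and the adult library 1535 barcodes and 5298315 UMIs (2546 and 1341). At these depths 3 counts in a class, used as the floor of detection, correspond to different CPM in each class, and every value carries its exact counting interval in the tables. The same 54532 gene IDs are listed for E18.5 and P14, and 49671 for the adult, of which 49446 are shared. The releases of the gene tables are not given in the sources used here. All results use shared IDs, which held 99.7, 99.7 and 100.0% of UMIs. Sharing an ID does not make the 2 gene tables count the same reads, so age and gene table coincide for the adult. Gene identity is the symbol and Ensembl ID of the deposited tables. Coordinates are from GENCODE release M21 on mm10 (GRCm38), which holds 54495 of the E18.5 and P14 IDs and 49412 of the adult IDs.

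Barcodes with under 500 genes or over 20% mitochondrial UMIs were removed (1, 0 and 3 barcodes, all for few genes). Scrublet scores, computed per library with scanpy, were ranked, and the expected share of top-scoring barcodes (0.8% per 1000 barcodes) was removed as doublets: 86, 43 and 19 barcodes were marked. This left 3184, 2274 and 1513 cells. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1 gave 32 clusters of the 3 libraries together, with no batch correction. Clusters were named from 23 marker sets fixed before the data were examined, as were all lists, comparisons, intervals and the rule for named genes. A name needed a marker of the class among the 10 genes with the highest fold (30 where none of the 10 was a marker), a mean marker z score of at least 0.8 and at least 3 markers detected in 5% of cells, with a fold pseudocount of 0.3 per 10000 UMIs. The class also needed the highest mean z score, or a place in the same group as the class that had it. Groups were the stages of the neuronal lineage, and fibroblasts with cartilage or bone cells. Clusters 6 and 7 took their names through such a group. These naming thresholds were chosen after seeing the data. They left 4 clusters unnamed (3, 24, 27 and 30). Cluster 24 (35 E18.5 cells) was led by Isg15, an interferon-stimulated gene, and Sult1e1, cluster 27 (25 E18.5 cells) by Osr1 and Acta2, and cluster 30 (9 P14 and 9 adult cells) by H2-Ab1 and Cd74. No cluster took the names of Bowman's gland, mast or erythroid cells.

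With 1 library per age no test of a difference between ages was possible, so none was run, and cells were not treated as replicates. For each class, UMIs were summed per library and divided by the class total over shared IDs (CPM). Sums have exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all of counting error only. Genes were ranked by the log2 ratio of CPM plus 10. Named genes were the 10 highest in each direction between E18.5 and adult for mature neurons and horizontal basal cells, the 6 highest for other classes with at least 30 cells in both libraries, and the 5 highest between P14 and adult for mature neurons. They had at least 100 CPM in the higher library and a class CPM there of at least 50% of that in all other cells. Receptor, ribosomal, mitochondrial, unnamed predicted and sex-linked control genes were excluded from that rule. Sustentacular cells fell under the minimum of 30 cells at P14 and adult and were described only. A ratio against a library at 0 is a lower bound against 3 counts.

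The 18 gene lists were olfactory transduction, receptor choice and trafficking, axon growth and guidance, presynaptic, immediate early and stress, respiratory chain, xenobiotic metabolism, odorant-binding and secreted, Notch pathway, basement membrane adhesion, injury-activated basal cell, S phase, G2 and M phase, antigen presentation and interferon-stimulated, imprinted and fetal growth, zonal, guanylate cyclase D neuron and 1 list that is not reported here. All members were found except Lcn13 and Lcn14 of the 22 odorant-binding genes. A list's value is the median log2 ratio of members with at least 10 CPM in 1 of the 2 libraries, with an interval from 200 Poisson draws and its percentile among 10000 random lists matched on mean expression where at least 3 members counted. Examples were the 2 highest and 2 lowest members with at least 50 CPM. Free RNA was estimated per class from markers of classes to which the cells do not belong. Receptors were called at 2 or more UMIs, and receptor and cell cycle shares were also taken after thinning cells to 1500 UMIs. Genes were said to jump in the adult when, in globose basal-, precursor- and immature neuron-like cells summed, their adult value lay at least 5-fold from P14, E18.5 and P14 lay within 2-fold of each other and the highest value reached 30 CPM, with a pseudocount of 2 CPM. Elsewhere they carry that name without meeting it class by class. That definition was set after seeing the data.

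The ranking, naming and list steps were tested on simulated class sums, with 49446 genes. These were Poisson draws from the mean of the E18.5 and adult profiles in each of 4 classes. All 100 genes changed 2-fold and all 100 changed 8-fold had the right direction in each class, with median absolute log2 ratios of 0.93 to 1.05 and 2.92 to 2.98. Among the genes named in the simulation, 20 of 20, 12 of 12, 20 of 20 and 12 of 12 had been changed. The draws held no effect of library, free RNA, class make-up or gene table, and naming left out the minimum against other cells. The simulation thus tests the steps under counting error only, not the named genes of the real data. Of 40 unchanged lists per class, 2, 4, 1 and 1 fell outside the central 95%, and the raised list reached percentile 99.99 or 100. Alternatives tried were a stricter filter (1000 genes, 10% mitochondrial), no filter, no doublet removal and the expected share doubled, resolutions of 0.5 and 2, each library clustered on its own, thinning, 4000 variable genes, other totals and scalings, a pseudocount of 1, other minimums, free RNA subtraction and other receptor and cycle thresholds. Choices added after seeing the data were cluster 11 alone or counted as immature, cluster 3 counted as mature, and adult-jump genes left out of lists. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and bedtools 2.31.1.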

Results

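The neuronal lineage shifted from dividing and immature stages at E18.5 to mature neurons in the adult. Among lineage cells, mature olfactory sensory neuron-like cells made up 10.1% (95% counting interval 8.43 to 12.1) at E18.5, 62.9% (60.5 to 65.2) at P14 and 78.8% (76.4 to 81.1) in the adult. Globose basal- or cycling-like cells fell from 28.1% (25.5 to 30.8) to 10.7% (9.29 to 12.3) and 5.78% (4.55 to 7.22). Neuronal precursor-like cells were 26.5, 11.7 and 7.30% of the lineage, and immature neuron-like cells 35.2, 14.7 and 8.11%. The split between these 2 classes is uncertain. Cluster 6, with 171 of the 296 precursor-like cells at E18.5, scored higher on immature neuron markers (mean z 1.29) than on precursor markers (0.88). Each age is 1 library, so no difference here has a replicate check, and every interval covers counting error only. How many E18.5 cells counted as mature depended strongly on the clustering, and 5 of the alternatives put that share between 0.494 and 1.56%. The P14 share exceeded the adult share with the stricter filter (65.1 against 62.4%) and with each library clustered on its own (68.1 against 65.7%).

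**Figure D1:**
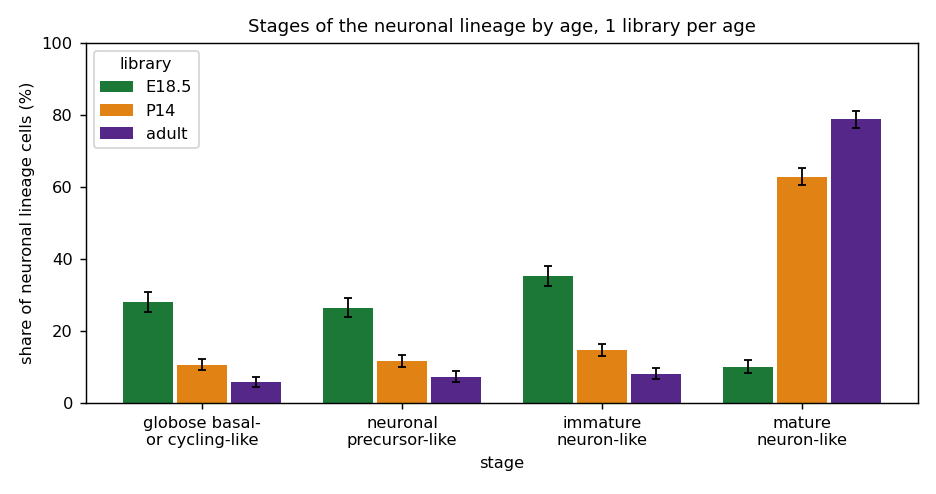
Share of neuronal lineage cells (%) in each of 4 stages for the E18.5, P14 and adult libraries. Bars are shares and error bars exact binomial 95% intervals of counting error, and the mature neuron-like share is 10.1% at E18.5, 62.9% at P14 and 78.8% in the adult.

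The cells around the neurons differed between libraries too. Lineage cells were 35.0% (33.4 to 36.7) of retained cells at E18.5, 73.8% (71.9 to 75.6) at P14 and 82.4% (80.3 to 84.2) in the adult. The order of P14 and adult turned with the stricter filter (90.5 against 83.0%), when thinned (90.2 against 80.9%) and with cluster 3 counted as mature (89.8 against 82.7%). Sustentacular-like cells, the supporting cells of this epithelium, were 16.2% (516 cells) at E18.5, 0.308% (7 cells) at P14 and 0 in the adult, where 3 cells would be 0.198%. Stromal, vascular and glial cells were 18.97, 4.05 and 0.330%, and respiratory cells 8.73, 0.132 and 0%. Vomeronasal neuron-like cells occurred at E18.5 alone (177 cells, 5.56%), with 0 at P14 (3 cells would be 0.132%) and 0 in the adult. Tuft-type microvillar-like cells were absent at E18.5 (3 cells would be 0.0942%), 0.308% at P14 and 4.76% (3.74 to 5.96) in the adult, while ionocyte-type microvillar-like cells stayed between 0.793 and 1.80%. Immune cells were 2.32, 1.36 and 8.79%, and B cell-like cells (18 cells, 1.19%) occurred in the adult alone. Unnamed clusters, left out by a naming threshold set after seeing the data, held 2.20, 16.4 and 0.991% of cells. The largest of them, cluster 3, held 364 P14 cells with a median of 1848 UMIs and was led by Pcdh11x, Hist2h4 and Mapk15. It scored highest on mature neuron markers (mean z 1.03), with 12 of them detected. It stayed unnamed because none of these was among its 30 genes with the highest fold.

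In mature neuron-like cells, the calcium-binding protein gene S100a5 was among the genes with the highest ratios between E18.5 and adult. S100a5 (ENSMUSG00000001023, chromosome 3, 90608523 to 90611780 on mm10) had 845 CPM (790 to 903) at E18.5, 10055 (9953 to 10158) at P14 and 16232 (16084 to 16380) in the adult, 19.2-fold (18.0 to 20.6) from E18.5 to adult. Pcp4l1 rose from 73.3 to 1127 and 1215 CPM, the synaptic scaffold gene Dlg2 from 13.7 to 253 and 278, and the cell survival gene Bcl2 from 5.86 to 88.7 and 138. The ion channel subunit genes Scn4b (20.5, 320 and 294 CPM) and Kcns3 (6.84, 124 and 140) and the neuropeptide gene Pth2 (14.7, 125 and 189) were likewise low at E18.5 and high at both later ages. The interferon-inducible gene Ifi27 differed mostly between P14 and adult, where age and gene table coincide, with 5.86, 15.4 and 165 CPM. On the other side stood Ndn, an imprinted gene (ENSMUSG00000033585, chromosome 7, 62346569 to 62350262), with 106 CPM at E18.5, 5.12 at P14 and 0 counts in the adult, at least 100.2-fold lower against a floor of 3 counts. The G protein subunit gene Gng3 went from 342 to 33.2 and 26.0 CPM, the intermediate filament gene Prph from 211 to 38.3 and 14.7, the AMPA receptor partner gene Cnih2 from 203 to 68.5 and 15.1, and Ly6h from 386 to 90.6 and 39.999. Hist3h2ba (925, 214 and 106), Bglap3 (106, 15.4 and 5.96) and Marcksl1 (676, 192 and 91.6) did likewise. Their E18.5 to adult ratios lay between 7.38 and 17.9.

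**Figure D2:**
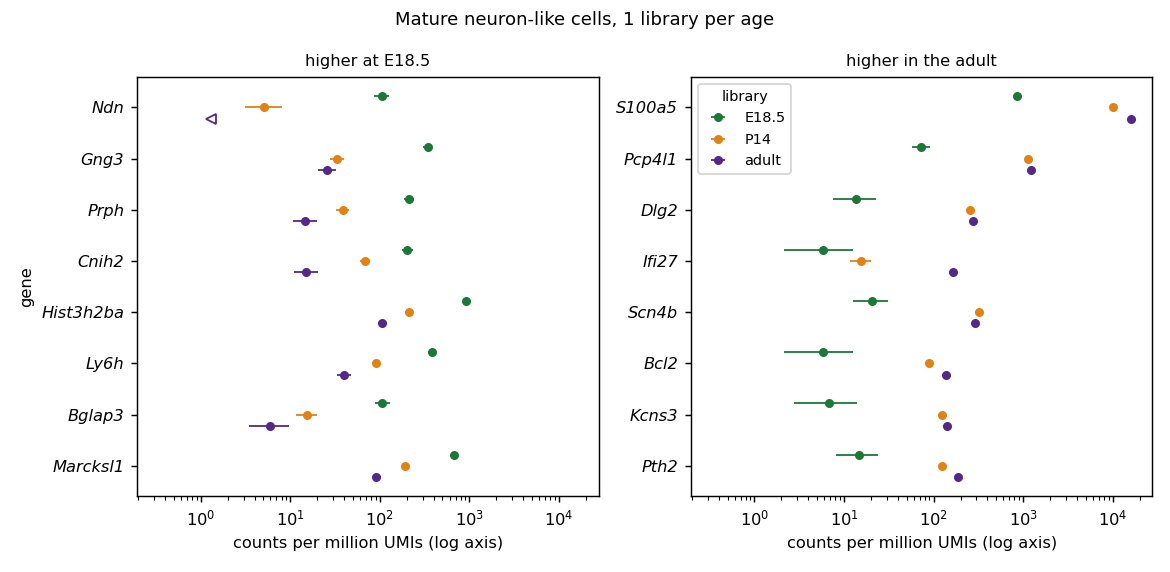
CPM (log axis) in mature neuron-like cells for genes named by the fixed rule, without those whose values step with the gene table, in the E18.5, P14 and adult libraries. Points are class sums, lines exact Poisson 95% intervals, and open triangles the upper limit of a library at 0; S100a5 stands at 845, 10055 and 16232.

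These mature cells fell in different clusters in the 3 libraries. Clustering had no batch correction, and whether the split follows maturation, library, depth or gene table was not tested. Of 113 E18.5 cells, 109 lay in cluster 11, which held 79 P14 and 50 adult cells, while adult cells were mostly in clusters 2 (560) and 5 (295) and P14 cells in cluster 0 (731). Depth differed too, with median UMIs of 9810, 2893 and 1973.5. Within cluster 11 alone, an added comparison chosen after seeing the data, the transduction list no longer differed (median log2 ratio of E18.5 over adult 0.07, interval -0.23 to 0.20), against -1.45 in all mature cells. The genes named by the fixed rule within cluster 11 were Ndn (107, 7.33 and 0 CPM), Nap1l5 (202, 78.8 and 15.4), Bglap3 (108, 66.0 and 12.3) and the potassium channel gene Kcna5 (213, 163 and 37.0) at E18.5. Car2 (61.2, 53.2 and 1228 CPM), Bcl2 (4.94, 103 and 170), Cwc22 (18.8, 165 and 176) and Dynlt1c (15.8, 20.2 and 105) were higher in the adult; Mef2b, Kctd17, Tonsl and Srp54c, treated with P14 against adult, completed the 12. Bglap3, Kcna5, Car2 and Dynlt1c differed by under 2-fold between E18.5 and P14 in this cluster. On a log scale the larger part of their difference lay between P14 and adult, where age and gene table coincide. Most genes named in all mature cells differed less here, with log2 ratios of -1.45 (S100a5, against -4.25), -0.85 (Pcp4l1, -3.88), -1.32 (Dlg2, -3.60), -0.76 (Scn4b, -3.32), -1.27 (Kcns3, -3.16) and -0.61 (Pth2, -3.01). Car2 is a marker of the guanylate cyclase D neurons, and 1 of the 8 genes of that list passed the minimum here (log2 ratio -4.12).

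Gene lists fixed before the data were examined moved apart in mature neuron-like cells. Olfactory transduction genes were lower at E18.5 than in the adult (median log2 ratio -1.45, interval -1.57 to -1.26, 1 of 14 higher, percentile 0 of 10000 matched random lists), led by Ric8b (138 against 632 CPM) and the channel subunit gene Cnga4 (124 against 498). Imprinted and fetal growth genes were higher at E18.5 (1.97, 1.68 to 2.15, 6 of 8), with Meg3 at 187, 4.05 and 0 CPM. Respiratory chain genes were higher at E18.5 in 16 of 17 cases (0.63, percentile 99.3), among them Cox6c (1340 against 690.5 CPM) and Cox7a2 (1394 against 730). Antigen presentation and interferon-stimulated genes were lower at E18.5 (-0.91, 3 of 10 higher, percentile 0.03), although B2m went the other way (184, 64.7 and 74.7 CPM). The axon list (0.34, 15 of 26) mixed Gap43 (1552, 324 and 251 CPM) and Dpysl3 (210, 78.2 and 50.9), both typical of growing axons, with Epha5 (62.5, 503 and 468) and Kirrel2 (64.5, 478 and 431), which sort axons in the bulb. In cluster 11 alone, Gap43 (log2 ratio -0.23) and Dpysl3 (-0.61) turned the other way, as did the axon (-0.25) and antigen presentation lists (0.03). Odorant-binding genes (1.66, 3 of 4) and xenobiotic genes (0.46, 8 of 11) were higher at E18.5 in these neurons. Both lists are made mostly of genes typical of other cells, but Nqo1 of the xenobiotic list had 2000, 1298 and 2222 CPM here. After subtraction of free RNA the xenobiotic value was -0.01. The remaining lists stood at 0.15 for receptor choice, 0.01 for presynaptic, -0.19 for immediate early, 0.48 for Notch, -0.50 for zonal and 0.22 for S phase genes. Lists with 1 or 2 genes above the minimum were basement membrane (-0.40), injury-activated (0.57), G2 and M phase (0.95) and guanylate cyclase D (-2.17).

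**Figure D3:**
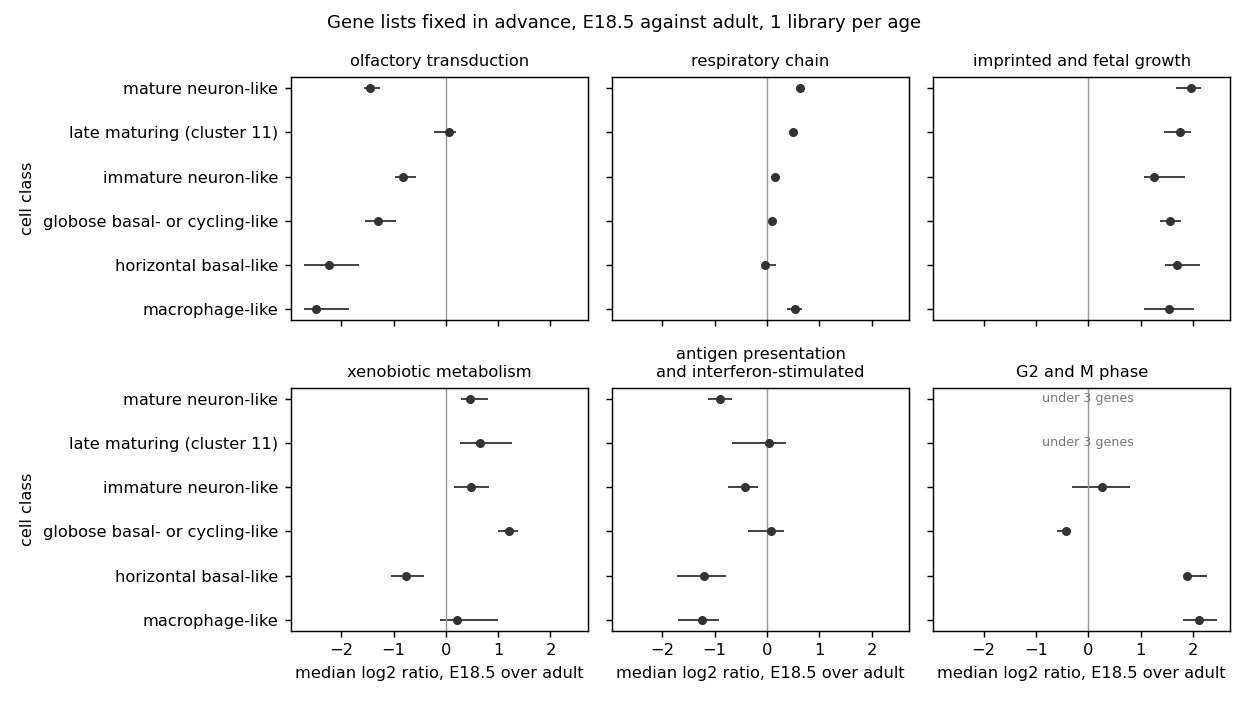
Median log2 ratio of E18.5 over adult for 6 fixed gene lists in 6 cell classes, 1 library per age. Points are medians and lines the central 95% of values under repeated Poisson draws of the counts, and the imprinted and fetal growth list lies between 1.25 and 1.97 in all 6 classes.

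Between P14 and adult, mature neuron-like cells differed less in these lists, with medians of -0.16 for transduction and -0.07 for respiratory chain genes. Kcna5 (174 against 33.3 CPM, 5.21-fold, 4.19 to 6.53) and Nap1l5 (294 against 74.4, 3.96-fold) were higher at P14. Nap1l5 also led cluster 0, which held 731 P14 and 77 adult cells. Ifi27 (15.4 against 165 CPM, 10.7-fold, 8.14 to 14.4) and S100a13 (27.2 against 106, 3.88-fold) were higher in the adult, and the antigen presentation list stood at -0.46 with 1 of 10 genes higher at P14. The other genes named by the fixed rule for this pair were among those that jumped in the adult library in globose basal-, precursor- and immature neuron-like cells summed. Mef2b (442, 152 and 0.351 CPM, 1 count in the adult), Kctd17 (134, 150 and 3.86) and Wdr27 (79.1, 102 and 0.351) were lower in the adult, and Tonsl (0.977, 0.539 and 260), Srp54c (0, 1.08 and 150) and Btf3l4 (32.2, 24.0 and 114) were higher. Adult counts were made on another gene table than those of E18.5 and P14, so age and gene table coincide for every difference between P14 and adult given here. Mef2b, Tonsl, Srp54c and Kctd17 were also among the genes named in the E18.5 to adult comparison. The adult to E18.5 ratio of Tonsl was 266-fold with an interval of 47.6 to 10525. An ID listed for E18.5 and P14 alone, Vps28, overlaps Tonsl. In globose basal-, precursor- and immature neuron-like cells summed, adding its UMIs at P14 took the adult to P14 ratio of Tonsl from 29.3 to 0.896.

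Immature neuron-like and precursor-like cells shared a group of genes that were lower in the adult than at E18.5. Of these, Id4, Nnat and Lsm7 differed by under 2-fold between E18.5 and P14 in both classes, and on a log scale the larger part of their fall lay between P14 and adult, where age and gene table coincide. The transcription regulator gene Id4 (ENSMUSG00000021379, chromosome 13, 48261228 to 48266026) had 2255 (2187 to 2325), 1426 (1349 to 1506) and 544 (477 to 617) CPM in precursor-like cells, 4.15-fold (3.64 to 4.74), and 311, 227 and 46.0 in immature neuron-like cells. The imprinted gene Nnat went from 458 to 349 and 83.5 CPM in precursors and from 101 to 53.4 and 20.2 in immature neurons. Lsm7, of the RNA decay machinery, went from 282 to 225 and 51.9 and from 270 to 240 and 68.1, and was 207, 143 and 32.3 CPM in all cells outside immature neurons. Rab3c, a vesicle gene, fell from 130 to 59.0 and 24.8 CPM in precursors. Ndn in immature neurons had 111, 6.92 and 5.52 CPM, with 3 adult counts and a ratio of 20.2 (6.85 to 98.4). The splicing factor gene Cwc22 was low at E18.5 and alike at the later ages, with 29.4, 272 and 236 CPM in immature neurons and 25.7, 248 and 226 in precursors. Dynlt1c (11.1, 34.6 and 112 in immature neurons) and Zbtb20 (44.9, 117 and 156 in precursors) were higher in the adult. Hbb-bt in precursors (129, 8.91 and 0 CPM, at least 19.1-fold) is a blood globin gene. Genes with the adult jump again ranked high, namely Mef2b (868, 764 and 0 CPM), Pola2 (123, 72.3 and 1.84), Tonsl (1.31, 2.52 and 265), Ptp4a1 (0, 0 and 153), Srp54c (0.654, 1.26 and 105) and Btf3l4 (41.5, 35.2 and 252) in immature neurons. In precursors, Pola2 stood at 163, 108 and 4.51 CPM, Ptp4a1 at 0, 0 and 237, Tonsl at 0.547, 2.23 and 212, Srp54c at 0, 0 and 113 and Btf3l4 at 30.1, 36.8 and 201. Transduction genes were lower at E18.5 in both classes (-0.82, 2 of 13 higher, in immature neurons and -1.01, 1 of 12, in precursors), and imprinted genes higher (1.25, 9 of 9, and 1.30, 9 of 10). Mature neuron-like cells were 3.55% of retained cells at E18.5, 46.4% at P14 and 64.9% in the adult. Free RNA from them would act in the direction of the transduction medians, so its part in these medians stays open. Median depth was 7605, 6442 and 5593 UMIs in immature neurons and 5901, 4823.5 and 5003 in precursors.

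Globose basal- or cycling-like cells carried a smaller G2 and M phase share at E18.5. At an equal depth of 1500 UMIs, 55.9% (50.2 to 61.5) had at least 2 such genes at E18.5, 83.5% (77.0 to 88.9) at P14 and 82.9% (72.0 to 90.8) in the adult. Thinning left out 0, 16 and 2 cells, and the unthinned shares were 75.1, 92.2 and 95.8%. The same share in mature neuron-like cells was 0, 0.867 and 0.306%, where 3 cells at E18.5 would be 2.65%. The marker set that named globose basal or cycling cells shares genes with the G2 and M phase list, Mki67 and Top2a among them. The share in that class thus depends in part on which clusters took the name. Top2a (475, 1106 and 1217 CPM) and Mki67 (90.2, 297 and 285) led this list, whose median was -0.43 (0 of 15 genes higher at E18.5, percentile 0.01), but -0.13 with each library clustered on its own, -0.20 with no doublet removal and -0.24 with the stricter filter, and the S phase list stood at -0.21 (4 of 15). Globose basal- or cycling-like cells had median depths of 9901, 4789 and 9937 UMIs and came from clusters 13, 14 and 18 in all 3 libraries. Cluster 13 held 151, 55 and 14 of them at E18.5, P14 and adult. Cluster 14 held 95, 73 and 33, and cluster 18 held 67, 52 and 25. Whether the G2 and M phase share follows age or this make-up of the class was not tested. The linker histone genes Hist1h1e (31.5, 189 and 197 CPM) and Hist1h1b (34.1, 151 and 144) rose with Cwc22 (36.0, 161 and 162). The long noncoding RNA Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) had 341 (321 to 362), 21.8 (14.4 to 31.7) and 2.80 (0.339 to 10.1) CPM, with 2 adult counts and a ratio of 122 (33.7 to 1008). The sulfotransferase gene Sult1e1 (456, 68.7 and 23.8 CPM) and Cdkn1c (340, 43.6 and 23.8), which restrains the cell cycle, were also higher at E18.5, as were Hes1 (52.0, 17.8 and 19.6) and Hey1 (87.4, 38.0 and 39.2) of the Notch list (0.30), a direction that free RNA subtraction turned for Hes1 and the list (both -0.04). The imprinted list stood at 1.56 with 12 of 12 genes higher. Cyp2g1 (108, 25.9 and 2.80 CPM, 2 adult counts) and the xenobiotic list (1.21, 16 of 18), typical of sustentacular cells, were higher at E18.5, as was Wfdc18 (145, 33.1 and 1.40 CPM, 1 adult count), which in other cells had 269, 462 and 5.82 CPM. Estimated free RNA in this class was 13.1, 12.2 and 5.08%. Pgk1 (461, 217 and 8.39 CPM), Pola2 (179, 169 and 23.8), Ptp4a1 (0, 0 and 288), Srp54c (0, 0.808 and 110) and Btf3l4 (33.7, 21.01 and 213) were among the adult-jump genes.

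Horizontal basal-like cells, named for the reserve stem cells of the epithelium, differed in imprinted, cell division and interferon-inducible genes. The class joined cluster 8 (240, 28 and 30 cells at E18.5, P14 and adult) and cluster 21 (63, 14 and 0), led by Scgb1c1 and Ccl20. No marker set separated respiratory basal cells, which were not excluded. Whether the differences follow age or this make-up of the class was not tested. At E18.5 the class carried the imprinted genes H19 and Cdkn1c. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) had 1072 (1029 to 1116), 52.2 (23.9 to 99.1) and 0 CPM, at least 37.1-fold lower in the adult against 3 counts, and Cdkn1c 965, 87.0 and 19.2 (2 adult counts, ratio 50.2, 13.9 to 414). Ndufa4l2, induced by low oxygen, had 999.9, 5.80 and 0 CPM (at least 34.7-fold), and the fatty acid binding gene Fabp5 438, 75.4 and 0 (at least 15.2-fold). Nt5dc2 (348, 58.0 and 0), Lgals7 (255, 5.80 and 0), Mfap2 (238, 29.0 and 0), Smoc2 (195, 23.2 and 0) and Wfdc18 (180, 23.2 and 0) were likewise at 0 in the adult, with bounds between 6.25 and 12.0. In the adult, the interferon-inducible gene Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) reached 692 CPM (542 to 872) from 12.9 (8.57 to 18.6) at E18.5 and 133 (84.6 to 200.2) at P14, 53.7-fold (34.3 to 86.4). Ly6a (22.6, 145 and 529 CPM), the lipopolysaccharide receptor gene Cd14 (5.52, 92.8 and 212), S100a6 (228, 899 and 2270) and Ifi27 (64.4, 209 and 519) rose in the same order. So did the detoxification genes Ces1d (74.6, 1149 and 1193 CPM), Aldh3a1 (45.6, 377 and 548) and Sult1d1 (81.9, 899 and 1471), although Sult1d1 was as high in other adult cells (1499). Pgk1 (338, 203 and 0), Ptp4a1 (0, 0 and 221) and Tonsl (3.22, 0 and 289) were among the adult-jump genes.

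**Figure D4:**
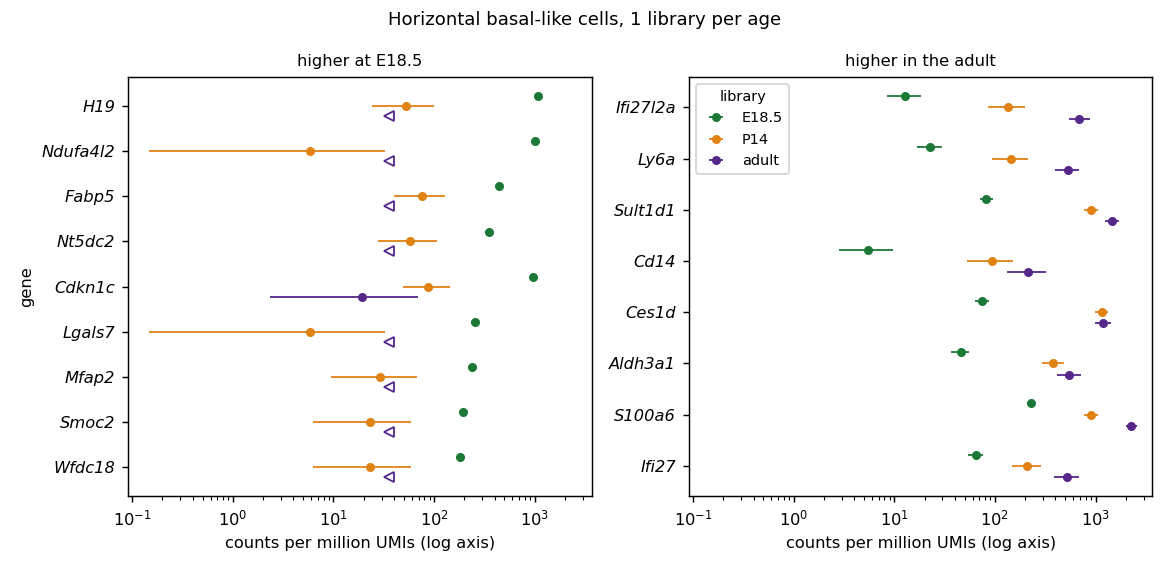
CPM (log axis) in horizontal basal-like cells for genes named by the fixed rule, without those whose values step with the gene table, in the E18.5, P14 and adult libraries. Points are class sums, lines exact Poisson 95% intervals and open triangles the upper limit of a library at 0; Ifi27l2a stands at 12.9, 133 and 692.

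The largest fixed list median in horizontal basal-like cells was that of transduction genes (-2.23, 1 of 10 higher at E18.5), which belong to neurons, and free RNA subtraction turned it to 1.75. Imprinted genes were higher at E18.5 (1.70, 13 of 13), as were G2 and M phase (1.88, 14 of 14), S phase (0.98, 13 of 14) and injury-activated genes (1.53, 5 of 6), the last led by Krtdap (166, 0 and 0 CPM). At equal depth, 16 of 303 E18.5 cells (5.28%) had at least 2 G2 and M phase genes, against 0 of 41 at P14 and 0 of 30 in the adult, where 3 cells would be 7.32 and 10%. Antigen presentation genes (-1.21, 0 of 12 higher at E18.5), with H2-D1 at 125, 452 and 750 CPM, and xenobiotic genes (-0.77, 6 of 25) were higher in the adult. Basement membrane adhesion genes stood at -0.05 (6 of 12), with Cd151 at 95.8, 116 and 260 CPM and Col17a1 at 127, 197 and 115. The adult value rests on 30 cells, all in cluster 8, and the free RNA estimate was 21.7, 13.9 and 16.4%, with median depths of 6399, 4331 and 3375 UMIs.

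Sustentacular-like cells could be described at E18.5 alone. They expressed Gstm1 (18869 CPM), Cbr2 (3562), Cyb5a (1594), Tst (1547), Cyp2a5 (914), Cyp2g1 (838), Por (762) and Ermn (602), genes of detoxification apart from Ermn. Mature neuron-like cells of the same library held 228 CPM of Gstm1 and 5.86 of Cyp2g1. Cluster 17 (147 cells) carried more Sult1c1 (1219 against 69.1 CPM), Fmo6 (394 against 3.86) and the water channel gene Aqp5 (732 against 186) than cluster 4 (369 cells), which carried more Gstm1 (24183 against 5503). Aqp5 is also in the fixed marker set of Bowman's gland, and gland cells within cluster 17 were not excluded. The 7 P14 cells had 3940 CPM of Cyp2g1, 4025 of Sec14l3 and 899 of Cyp1a2, against 838, 333 and 16.6 at E18.5, and are too few for a comparison. Genes named here were chosen after their values were seen, except where they belong to a fixed list or marker set.

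Macrophage-like cells carried more cell division genes at E18.5 and more genes of class II antigen presentation in the adult. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) had 79.7 CPM (53.4 to 114) at E18.5, 2347 (2008 to 2726) at P14 and 6324 (5977 to 6685) in the adult, 79.4-fold (55.0 to 119). H2-Eb1 (24.7, 494 and 3757), H2-Aa (98.9, 1894 and 6385) and Cd74 (629, 8125 and 24615) rose with it, and the antigen presentation list had a median of -1.25 with 0 of 19 genes higher at E18.5. Ly6c1 (0, 0 and 132 CPM, at least 16.0-fold) and Cd209a (0, 0 and 117, at least 14.2-fold) were at 0 in macrophage-like cells of the other libraries. Their difference rests on the adult library, where age and gene table coincide. At E18.5 stood the apolipoprotein gene Apoc1 (2102, 384 and 86.4), the cell division gene Birc5 (140, 0 and 0, at least 9.19-fold), Saa3 (118, 13.7 and 0, at least 7.75-fold) and the calprotectin gene S100a8 (1659, 0 and 0, at least 108.8-fold), the last also a fixed neutrophil marker. G2 and M phase genes (2.12, 14 of 14) and S phase genes (1.08, 12 of 12) were higher at E18.5. At equal depth, 11.4% of E18.5 cells against 1.47% of adult cells had at least 2 G2 and M phase genes, with overlapping counting intervals. Immediate early genes were higher in the adult (-0.76, 1 of 18 higher at E18.5), among them Nr4a1 (10.99, 27.4 and 55.9 CPM) and Klf4 (19.2, 54.9 and 76.3). Pgk1 (302, 124 and 10.2) and Ftl1-ps1 (217, 165 and 10.2) were among the adult-jump genes, although Pgk1 differed between E18.5 and P14 here. The P14 values rest on 22 cells, against 70 and 72, and the all-gene median of this class was -0.09 by CPM, 0.15 without mitochondrial, ribosomal and globin genes in the total and -0.16 by median of ratios.

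With receptors called at 2 or more UMIs, most mature neuron-like cells carried 1 olfactory receptor in each of the 3 libraries. A receptor at 2 or more UMIs was found in 91.2% (84.3 to 95.7) of mature neuron-like cells at E18.5, 92.2% (90.4 to 93.8) at P14 and 87.3% (85.0 to 89.3) in the adult, and 9.73, 9.48 and 8.15% had at least 2. When 1 UMI was enough for a call, 59.3, 77.6 and 73.0% had at least 2. At an equal depth of 1500 UMIs, which left out 0, 17 and 329 cells, those with at least 2 were 3.54, 5.01 and 5.05%. Immature neuron-like cells at E18.5 had at least 2 receptors in 19.1% (15.3 to 23.3) of cases, against 13.8% (9.72 to 18.7) and 10.9% (5.56 to 18.7). At equal depth these were 8.91% (6.28 to 12.2), 2.03% (0.663 to 4.68) and 5% (1.64 to 11.3). Samples of 113 mature cells held 89 receptors at E18.5, 96.2 (89 to 103) at P14 and 87.3 (79 to 95) in the adult. Receptors numbered Olfr543 to Olfr691, a block with most class I receptors, held the receptor with the most UMIs in 12.6% (6.89 to 20.6) of receptor-bearing E18.5 cells, 16.6% (14.4 to 19.1) of P14 cells and 28.1% (25.1 to 31.3) of adult cells. At equal depth the block shares were 12.5, 16.5 and 29.8%. Counting in each cell only the receptor with the most UMIs, the most frequent in adult neurons were Olfr672 (15 of 982 cells), Olfr77 (13), Olfr728 (11), Olfr348 (10) and Olfr653 (10), of which Olfr672 and Olfr653 are in the block. At P14 they were Olfr536 (8 of 1055), Olfr961 (8), Olfr30 (7), Olfr411 (7) and Olfr544 (7), and at E18.5 Olfr1274-ps, Olfr869 and Olfr965 (3 of 113 each), Olfr1042 (2) and Olfr1253 (2). Olfr728 (chromosome 14, 50133758 to 50142680) was at 2 or more UMIs in 11 adult cells and 0 of the others, and Olfr672 in 17 adult cells, 9 at P14 and 1 at E18.5. Age and gene table coincide for the adult receptor counts, and the dissected area may have differed between libraries. Whether either contributed to the adult block share or to Olfr728 was not tested. Trace amine receptor genes were found in 4, 13 and 8 mature cells.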

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

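All tests in this part were chosen only after the result was seen, except the depth and nuclear RNA tests of the span pattern. UMIs on gene IDs outside the shared set, which no comparison used, numbered 73370 (0.292%) at E18.5, 31490 (0.337%) at P14 and 608 (0.0115%) in the adult, above the 3 counts that a listing of 0 allows. Ndufb1-ps led them at E18.5 (11852) and P14 (4102) and Micalcl in the adult (140).

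In globose basal-, precursor- and immature neuron-like cells summed, 16 genes were lower and 20 higher in the adult library than at P14 by 5-fold or more, with E18.5 and P14 within 2-fold, among them Mef2b, Pgk1 and Pola2 (lower) and Ptp4a1, Tonsl and Srp54c (higher). The same criterion with E18.5 apart from the other 2 gave 15 and 3 genes. The first explanation, that the missing reads were counted on an overlapping ID listed for E18.5 and P14 alone, was argued against for the set, since adding those UMIs left the median adult to P14 ratio of the 8 overlapping genes at 11.35 (18.54 before). It held for 2 of the 8, Tonsl with Vps28 (29.3 to 0.896) and Gm49342 with Pnp (16.9 to 1.31). A second explanation, written after that failure, is that reads are lost where such an ID overlaps, and 40% (19.1 to 63.9) of the genes higher in the adult overlapped one, against 0.687% (0.489 to 0.937) of genes with no step, while 12 of the 20 remain without it. Of the genes lower in the adult, 43.75% of gene and class pairs (7 of 16) were also lower by 5-fold or more in horizontal basal or macrophage-like cells, as another gene table could produce. These folds were taken against a floor of 3 adult counts. All 16 pairs had under 3 adult counts. The other 9 pairs were too low at E18.5 and P14 to reach 5-fold over that floor whatever their adult value. The 43.75% is thus set by the floor and cannot decide, so this explanation stays open. Of all step genes, 86.11% moved 3-fold in each of the 3 lineage classes (31 of 36). For Tonsl and Gm49342, ratios of 0.896 and 1.31 after the addition above argue against a change of expression with age. For the other step genes such a change cannot be told apart, because age and gene table coincide.

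Sustentacular-like cells were nearly absent at P14 and adult. Lysis in the loaded suspension could have released their RNA. The summed fixed markers in mature neuron-like cells were 40.18 CPM at P14 and 45.26 in the adult, against 142.6 at E18.5, but Cbr2 gave 109 of the 146 E18.5 UMIs and was found in other cells too (1013 CPM). Without Cbr2 the sums were 16.2, 34.4 and 36.1 CPM in the same order, so lysis stays open. Doublet removal is argued against, since the highest share was 0.4316% when that step or the barcode filter was left out. The barcode filter used here had removed only 0 P14 and 3 adult barcodes, so its test could hardly have come out otherwise. A larger share of neurons alone is argued against by the number per ionocyte-type cell, at 10.98 at E18.5, 0.1707 at P14 and at most 0.3599 in the adult. The authors' filtering of barcodes before deposit, yield of the dissociation, the dissected area and age itself stay open and were not tested.

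Genes with a long genomic span were lower at E18.5 than at P14 (rank correlation of span with the log2 ratio -0.38 in globose basal-, precursor- and immature neuron-like cells), with values of 0.02, 0.05 and 0.01 between P14 and adult. Lower depth per cell is argued against, since within E18.5 the deepest against the shallowest cells gave -0.09437, -0.04932 and -0.008364 in the same order. A large gain in the share of nuclear RNA is argued against in these classes by Malat1, between 0.8901 and 1.143 times its E18.5 level. At P14 Malat1 was 1.143 (1.125 to 1.161) in globose basal- and 1.12 (1.106 to 1.134) in precursor-like cells, so a small gain stays open there. Neat1 was mixed at P14 (2.25 in immature neurons, 1.57 in precursors and 0.561 in globose basal cells). A larger nuclear share stays open in macrophage-like cells, where Malat1 was 1.81 (P14) and 2.11 (adult) times its E18.5 level. A change of the neuronal lineage alone is argued against by cells outside it, with -0.2067 in macrophage-like cells between E18.5 and adult and -0.24 in horizontal basal-like cells between E18.5 and P14, although the latter was weaker between E18.5 and adult (-0.1007) and positive between P14 and adult (0.1025). Nuclear RNA could account for the macrophage value, and in horizontal basal-like cells at P14 Malat1 was 1.099 and Neat1 3.18 times its E18.5 level. Age and library preparation stay open and were not tested, so the cause is not known.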

How the results depend on the processing

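No paired analysis was possible because each age has 1 library. Cluster 11 alone or counted as immature, cluster 3 counted as mature and adult-jump genes left out were chosen only after the result was seen. Among shares that answer a comparison 96 of 153 alternative values stayed within the counting interval and 57 moved; among the list medians that do so 50 of 64 stayed, 13 moved and 1 reversed. Of other values, 822 of 973 list medians, 200 of 264 shares and 1170 of 1475 single gene ratios stayed, with 15 list medians and 11 genes reversed. The cause was not tested for any moved or reversed value below, apart from settings that change depth or the number of UMIs or genes required, which act by construction. The sustentacular share at E18.5, the receptor block shares at E18.5 and adult and the macrophage antigen presentation median stayed within their intervals in every alternative run.

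The mature share of the lineage at E18.5 (10.1%) was the least stable value. It was 1.55% with the stricter filter, 13.3% with no doublet removal, 0.498% at resolution 0.5, 0.494% at resolution 2, 1.56% thinned to 1500 UMIs, 0.592% with 4000 variable genes and 0.359% with cluster 11 counted as immature. At P14 (62.9%) it was 65.1% with the stricter filter (within its interval), 68.2% with no doublet removal, 65.3% at resolution 2, 68.1% with each library clustered on its own, 60.2% thinned, 47.3% with 4000 variable genes, 58.2% with cluster 11 as immature and 69.5% with cluster 3 as mature. In the adult (78.8%) it was 62.4% with the stricter filter, 81.3% with no doublet removal, 65.7% clustered on its own, 66.6% thinned, 74.3% with 4000 variable genes and 74.8% with cluster 11 as immature. In each of these the E18.5 share stayed the lowest of the 3, but the order of P14 and adult was the other way round with the stricter filter (65.1 and 62.4%) and with each library clustered on its own (68.1 and 65.7%).

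The lineage share of all cells at E18.5 (35.0%) was 38.4% with the stricter filter, 27.7% with no doublet removal, 31.6% and 31.8% at resolutions 0.5 and 2, 37.9% clustered on its own and 37.1% with 4000 variable genes. At P14 (73.8%) it was 90.5, 71.5, 71.4, 67.9, 57.7 and 60.4% in the same order, 90.2% thinned and 89.8% with cluster 3 as mature. In the adult (82.4%) it was 83.0% with the stricter filter, 80.9% thinned, 82.7% with cluster 3 as mature (each below P14), 79.6% with no doublet removal, 79.1% and 76.0% at resolutions 0.5 and 2 and 61.2% clustered on its own. Sustentacular-like cells at P14 were 0% when that library was clustered on its own.

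Mature cells with at least 2 receptors were 59.3, 77.6 and 73.0% at E18.5, P14 and adult when 1 UMI called a receptor, 6.16% at P14 and 3.97% in the adult with 3 UMIs, and 3.54, 5.01 and 5.05% when thinned. In cluster 11 alone the adult value was 6% and the P14 share of the Olfr543 to Olfr691 block 19.2%. Globose basal or cycling cells with cycle genes were 69.0 and 91.5% (E18.5 and P14) with 1 or more genes, 46.3 and 70.1% with 3 or more, 72.0% at P14 with S phase genes, and 75.1, 92.2 and 95.8% at full depth.

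For list medians (log2, E18.5 over adult), transduction in mature neurons was -1.74 with each library clustered on its own and 0.067, reversed, in cluster 11 alone. The imprinted list in immature neurons was 0.64 with no minimum CPM and 2.26 with a pseudocount of 1. In horizontal basal cells the xenobiotic list was -1.06 with the minimum doubled, -0.41 with none and -1.25 with free RNA subtracted, and antigen presentation -1.93 with a pseudocount of 1. G2 and M phase genes in globose basal or cycling cells were -0.13 clustered on its own, -0.35 with free RNA subtracted and by median of ratios, -0.20 with no doublet removal, -0.24 with the stricter filter and -0.36 without mitochondrial, ribosomal and globin genes in the total. The all-gene median moved by over 0.1 for horizontal basal cells (0.08 by CPM, -0.08 by median of ratios) and macrophages.

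Other reversals were as follows. Cluster 11 alone gave Acsm4 -0.093, Dpysl3 -0.61, Gap43 -0.23, Igf2bp3 0.026, Tapbp 0.49, antigen presentation 0.032 and axon genes -0.25. Each library clustered on its own gave Acsm4 -0.073, Nqo1 0.16 and odorant-binding genes of horizontal basal cells -0.39. Free RNA subtraction gave -0.011 for Cdkn1c in immature neurons, -0.078 for Gstm1 in horizontal basal cells, and -0.035 for Hes1 and for the Notch list in globose basal cells. It also gave 0.44 (axon) and 0.48 (receptor choice) in macrophages, -1.07 (odorant-binding) and 1.75 (transduction) in horizontal basal cells, -0.75 for odorant-binding genes in immature neurons, and for xenobiotic genes -0.31 in immature neurons, -0.25 in precursors and -0.0093 in mature neurons. The xenobiotic list in precursors was -0.0066 with the minimum doubled, axon genes in horizontal basal cells -0.10 as a mean of per-cell CPM, Ung in globose basal cells -0.22 with no doublet removal, and the Notch list there -0.092 with no minimum.

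Of the 20 genes named in mature neurons, between 12 and 20 were named again under the planned settings and 8 in cluster 11 alone. In other classes the fewest were 15 of 20 in horizontal basal cells (free RNA subtracted), 6 of 12 in immature neurons (minimum doubled), and 5 of 12 in precursors (no minimum), globose basal cells (minimum doubled) and macrophages (each library clustered on its own). The stricter filter gave no gene values for mature neurons or horizontal basal cells, which fell under 30 cells, and the alternatives for sustentacular genes gave none, since P14 and adult had 7 and 0 cells. Depth limits the adult most, where 390 barcodes lay under 1500 UMIs, against 153 at P14 and 0 at E18.5.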

Other observations

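All tests in this part were chosen only after the result was seen. Genes of glycolysis and of the response to low oxygen were higher at E18.5 than at P14, 2 libraries counted on the same gene table. Over 19 list genes, the median log2 ratio was 1.22 (16 of 16 genes higher) in globose basal- or cycling-like cells, 0.49 (12 of 14) in precursor-like cells, 0.4268 (12 of 15) in immature neuron-like cells, 0.45 (15 of 19) in horizontal basal-like cells and 0.71 (15 of 15) in cluster 11. The lowest percentile was 99.98 among random lists matched on expression and 99.93 among those matched on genomic span too. Ldha, Eno1, Ndrg1, Ndufa4l2 and Car9 had been seen and were left out of these values, and the result of all 24 genes had been seen before that of the 19, so the 19 are not an independent check. Between P14 and adult the medians were 0.02, 0.01, 0.03, 0.67 and -0.10. A lower oxygen supply before birth is a possible explanation, but handling of the tissue before capture is not given in the sources used here and was not tested.

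A few receptor transcripts appeared already in precursor-like cells. Olfr1372-ps1 at 2 or more UMIs was in 20 of 296 precursor-like cells at E18.5 (6.76%, 4.18 to 10.2), 2 of 196 at P14 (1.02%) and 5 of 91 in the adult (5.49%), against 2.65, 0.284 and 0.713% of mature neuron-like cells. Olfr482 was in 11 of 296 (3.72%) at E18.5 and 2 of 91 (2.20%) in the adult. Both were chosen after their values were seen. Shared barcode sequences between libraries were few, at 11, 8 and 5 for the 3 pairs.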
